A study of Homo sapiens with 10 samples.

How the data were processed

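Human breast tissue fixed in formalin and embedded in paraffin was macrodissected into epithelial and stromal fractions, per the labels' protocols, and bulk RNA was sequenced from regions of ductal carcinoma in situ (DCIS, tumour cells still inside the ducts) and invasive ductal carcinoma (IDC). RNA came from a kit for fixed tissue (AllPrep DNA/RNA FFPE). Libraries were made with TruSeq RNA Access, in which DNA probes pull down coding transcripts, per the labels' protocols. The extraction text speaks of the epithelial fraction, while 4 libraries are labelled as stromal; the groups here follow the sample labels. These give 4 groups: DCIS epithelium (n = 2), IDC epithelium (n = 4), DCIS stroma (n = 2) and IDC stroma (n = 2). The 10 libraries carry 6 patient labels.

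The deposited table holds TPM, the abundance of transcripts corrected for their length and scaled to the same sum in every library, for 57820 genes in the 10 libraries. A value of the authors' TPM is therefore a share of that library's length-corrected total and the number of reads behind it is unknown. FastQC, STAR and RSEM are named in the submitters' processing notes, without versions, together with the builds GRCh37 and hg19; the annotation is not given in the sources used here. TPM keeps no depth, so no counting interval or detection floor was computed, and a value of 0 is given as listed at 0. Of the genes tested, 3751 (21.5%) were listed at 0 in at least 1 library. The reference used here for names, gene types and transcript lengths (GENCODE 29) is on another build, so no coordinates are printed. It matched 51996 of the 57820 identifiers to a symbol, and 16960 of those tested. Sex-linked genes (480 entries) were left out. The table held 0 columns of other samples.

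The following choices were made before the data were examined, unless stated otherwise. Values were taken as log2(TPM + 1). Genes with a mean of at least 1 TPM over the 10 libraries were tested, 17473 in all, of which 14370 (82.2%) were protein-coding. A log2 difference on this scale understates the change of low genes. One linear model with the 4 group means was fitted with limma 3.58.1 in R 4.3.3, with the patient label as a random block (duplicateCorrelation), a trended prior variance, two-sided moderated tests and Benjamini-Hochberg adjustment; an adjusted p under 0.05 was the threshold. The estimated correlation within a block was 0.200, with 6 residual and 5.47 prior degrees of freedom. Differences are given with the model's standard error (SE) and group levels with the SD. There were 5 contrasts: IDC minus DCIS in epithelium, IDC minus DCIS in stroma, stroma minus epithelium with both stages weighted equally, the difference between the 2 stage contrasts, and their mean.

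The block rests on the labels, which give the DCIS and IDC regions of 4 pairs the same patient label. Stromal labels were kept as blocks of their own because the sources used here do not say how they relate to the epithelial ones. Residuals of paired libraries correlated at 0.244 and 0.254 in epithelium and at 0.135 in stroma, where groups of 2 libraries give both pairs the same value by construction. Samples of a group come from different patient labels. The p-values rest on a residual spread pooled over all groups, moderated by the prior variance, with a part shared within a label. They therefore do not measure the spread between patients alone. If stromal and epithelial labels that share a number belong to the same patient, the fraction contrast treats paired libraries as separate.

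Gene lists were 30 sets of cell type markers and pathway genes, with 479 members measured; 6 symbols matched no gene (PECAM1, MRC1, HIST1H2AE, HIST1H2BC, HIST1H3B and HIST2H4A). Each was tested against all other genes with limma's camera at a preset correlation between genes of 0.01, on values with the block correlation removed, and adjusted over the 30 lists of a contrast. The test was repeated with a correlation estimated from the residuals and with fry, which asks whether a list moves without comparing it with other genes. Genes were also adjusted over the list alone. The lists share few genes: FOXA1 is in the hormone receptor and apocrine lists, ACTG2 and CNN1 in the basal and smooth muscle lists, and KIT in the mast cell and lobule lists.

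Named genes followed a fixed rule for the stage contrasts and the fraction contrast. Among genes past the threshold with a mean of at least 5 TPM and the same direction in both pairs, or fractions that did not overlap, the 10 with the highest and the 10 with the lowest log2 difference were named. A direction with fewer than 5 was filled to 5 by unadjusted p, as genes that did not pass. The other contrasts named up to 5 per direction without a fill. From each list, up to 2 members past the threshold were to be named per direction, or else the 2 with the highest mean TPM. Not all of these members are given in the text, so a named member does not stand for its list. Features with clone-based names and genes whose presence varies between people were to be left unnamed. Genes outside this rule were chosen after their values were seen. They include SPRR1A, BMS1P22, COL1A1, features given by identifier, parents of pseudogenes, and list members past the threshold over the list alone.

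Alternatives were a pseudocount of 0.1 or 5, no expression filter or a mean of at least 5 TPM, quantile, median-of-ratios or upper-quartile scaling, no block, a fixed block, stromal and epithelial labels that share a number as one block, a prior variance without trend or robust, only the paired libraries, only the libraries of a fraction, and each library left out in turn. Chosen after seeing the data were protein-coding genes alone rescaled to the same sum, and genes of at least 200 nt or of unknown length. With 1 of 2 libraries of a group left out, the lone library is assumed to vary like the other groups. The epithelial and stromal groups were also regrouped at random, with 100 of the 210 possible splits drawn for stage and for fraction. Every split that parts as many label pairs as the real one was fitted as well, 10 for fraction and 16 for stage.

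The fit was tested on simulated data with 200 changed genes. In the epithelial stage contrast (16850 genes), 1.54% of genes changed by a log2 of 1 were recovered, 24.2% at 2 and 84.8% at 4, with 6 false calls. In the stromal stage contrast (16857 genes), these shares were 0%, 15.4% and 80.3%, with 5 false calls. In the fraction contrast (16880 genes), they were 1.49%, 34.8% and 87.9%, with 4 false calls. A list of 15 genes shifted by a log2 of 1 was called in each (camera adjusted p = 1.46e-07, 0.00014 and 3.24e-11) with 0 other lists. The genes were simulated independently of one another. In the data, the estimated correlation between the genes of a list was 0.343 for luminal, 0.677 for adipocyte and 0.804 for ribosomal protein genes. The simulation therefore cannot show how often camera at the preset correlation calls an unchanged list in these data. With an estimated correlation its adjusted p was 0.0233, 0.172 and 0.00985. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.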

Results

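The 10 libraries describe 2 fractions of breast tissue, epithelium and stroma, at 2 stages, DCIS and IDC. DCIS epithelium, DCIS stroma and IDC stroma have 2 libraries each and IDC epithelium has 4. Both epithelial DCIS libraries and both stromal DCIS libraries have an IDC partner under the same patient label, which makes 4 pairs; 2 epithelial IDC libraries have none. Libraries correlated with one another at Spearman coefficients of 0.830 to 0.932 across genes, and genes are not independent replicates. TPM is a share of each library's length-corrected total, and the number of reads is unknown. The probes pull down coding transcripts, so the share of a noncoding RNA need not be its share in the tissue. Protein-coding genes held 40.4% (IDC epithelium 1) to 58.0% (DCIS epithelium 1) of a library's TPM. Small nucleolar RNAs (snoRNAs, short guides for RNA modification) held 31.1% ± 3.03 (SD, n = 2) in DCIS epithelium, 38.3% ± 6.75 (n = 4) in IDC epithelium, 33.4% ± 0.198 (n = 2) in DCIS stroma and 33.0% ± 4.61 (n = 2) in IDC stroma. On the first principal component, with 24.0% of the variance, DCIS stroma 1 lay at 164 and the other libraries between -33.8 and 10.3.

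The first comparison asks what separates the stromal from the epithelial fraction. Fat cell genes were higher in stroma than in epithelium. FABP4, a fatty acid carrier of fat cells, stood at 717 ± 620 TPM in DCIS stroma and 317 ± 160 in IDC stroma (SD, n = 2 each), against 52.0 ± 44.0 in DCIS epithelium (n = 2) and 146 ± 66.0 in IDC epithelium (n = 4). CD36, a receptor for fatty acid uptake, stood at 475 ± 317 and 299 ± 15.5 in stroma against 59.9 ± 5.22 and 143 ± 43.8 in epithelium. Stroma minus epithelium, the log2 difference was 2.40 ± 0.58 (SE) for FABP4 and 1.96 ± 0.38 for CD36. All 16 measured adipocyte markers were higher in stroma, with a median log2 difference of 2.25 (camera adjusted p = 2.94e-19, and adjusted p = 0.668 with an estimated correlation). Adjusted over the list alone, 15 of the 16 passed, among them PLIN1, which coats fat droplets (2.84 ± 0.61), and LPL, the lipase that releases fatty acids from lipoproteins (2.16 ± 0.46). Over all genes none passed (adjusted p = 0.340 for FABP4 and 0.216 for CD36).

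**Figure D1:**
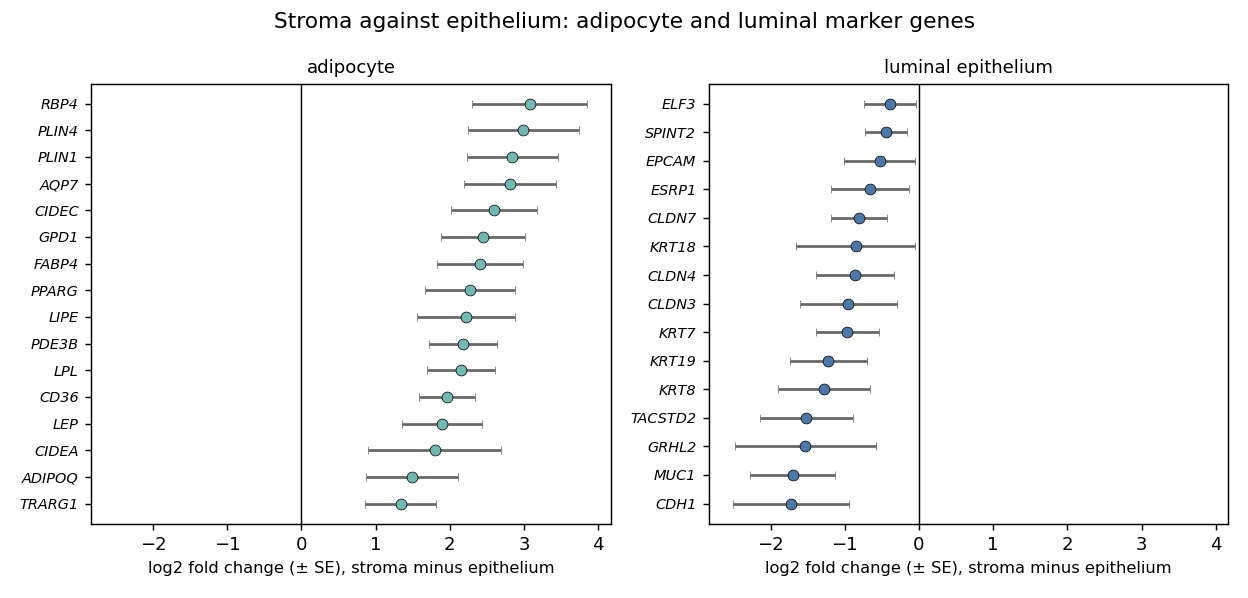
Log2 difference (stroma minus epithelium, x axis, log2 of TPM + 1) with its standard error for each measured marker of fat cells (left) and luminal epithelium (right). All 16 fat cell markers lie above 0 and all 15 luminal markers below 0.

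Epithelial and cell division genes were lower in stroma. All 15 luminal epithelium markers were lower (median -0.95, adjusted p = 9.27e-07), among them the surface mucin MUC1 (-1.70 ± 0.57). The proliferation list was lower in 26 of 28 members (median -0.88, adjusted p = 6.71e-06), with the kinetochore gene CENPF at -2.02 ± 0.62 and the topoisomerase TOP2A at -1.03 ± 0.80. The hormone receptor program was lower in 14 of 16 (-0.72, adjusted p = 0.0012), with the secretory regulator XBP1 at -1.54 ± 0.42, and the apocrine list in 9 of 12 (-0.47, adjusted p = 0.0159). With an estimated correlation, the adjusted p was 0.668 for the luminal and apocrine lists, 0.674 for proliferation and 0.686 for the hormone receptor program, and 0 members of these lists passed adjusted over the list alone. The invasion-associated matrix list, genes of remodelled tumour stroma, was lower in the stromal fraction in 17 of 19 members (-0.91, adjusted p = 0.000143, and adjusted p = 0.686 with an estimated correlation). Of these, the stromal protease MMP11 (-2.95 ± 0.68) was the 1 that passed adjusted over the list alone, and POSTN, a matrix protein of activated fibroblasts, had -1.64 ± 0.73. The gelatinase MMP2, with the highest mean TPM of the list, lay the other way (0.325 ± 0.528). The luminal and proliferation calls held whichever library was left out. The hormone receptor call was lost without DCIS epithelium 2 or IDC stroma 1 (adjusted p = 0.236 and 0.127). The apocrine call was lost without these (0.134 and 0.0597), without DCIS stroma 1 (0.0542) and with paired libraries only (0.220), and the invasion call without IDC stroma 2 (-0.271, adjusted p = 0.152).

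Vessel, nerve and blood markers were higher in stroma, and T cell, B cell, plasma cell and both MHC lists lower. All 15 endothelium markers were higher (median 0.54, adjusted p = 0.0021), with the clotting factor VWF at 1.02 ± 0.37, as were all 10 Schwann cell markers (0.75, adjusted p = 0.00474), with the myelin gene MBP at 1.85 ± 0.64. The erythrocyte list (1.73, 3 of 4, adjusted p = 0.0306) had HBB as the 1 that passed adjusted over the list alone. The immediate early and stress list was higher as well (0.60, 16 of 20, adjusted p = 0.00771). B cell markers were lower (-1.04, 12 of 14, adjusted p = 5.15e-05), with the kinase BLK the 1 that passed adjusted over the list alone. T cell (-0.77, 13 of 14, adjusted p = 0.00105), MHC class II (-0.68, 11 of 12, adjusted p = 0.00525), MHC class I (-0.43, 14 of 16, adjusted p = 0.00734) and plasma cell lists (-0.44, 12 of 15, adjusted p = 0.047) were lower, and so were ribosomal protein genes (-0.30, 29 of 33, adjusted p = 0.00474). With an estimated correlation none of these held, with adjusted p from 0.668 for the Schwann cell list to 0.788 for the plasma cell and ribosomal lists. The 14 other lists did not pass, fibroblast matrix among them (0.10, 12 of 20, adjusted p = 0.525). The B cell call held whichever library was left out, with a median of -1.59 to -0.561 over these and the other settings. Its score over the list was 4.37 in DCIS epithelium 1 and 0.84 to 1.77 in the other libraries, among which the fractions overlapped. Of the other 9 calls of this paragraph, 5 were lost without DCIS epithelium 1 (adjusted p = 0.320 to 0.414), 6 without DCIS stroma 1 (up to 0.926), and 5 without IDC stroma 2 (up to 0.512). DCIS stroma 2 decided 2 (0.274 and 0.549), IDC stroma 1 decided 2 (up to 0.157), and IDC epithelium 2, 3 and 4 decided 1 each (0.137, 0.110 and 0.0643). Without DCIS stroma 1 the plasma cell median was 0.0275, and each of the 3 scalings also ended that call (adjusted p = 0.0598 to 0.0653), as did a pseudocount of 5, no expression filter and protein-coding genes alone (0.0563 to 0.136). The ribosomal call was lost with paired libraries only (0.212) and the erythrocyte call without an expression filter (0.165).

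Among single genes that separated the fractions without overlap, none of the named protein-coding ones passed over all genes. FHL1, a LIM protein of muscle and connective tissue, had 234 to 829.2 TPM in stroma and 27.0 to 80.4 in epithelium (log2 difference 2.93 ± 0.49, adjusted p = 0.105). The reductase AKR1C1 (3.06 ± 0.52, adjusted p = 0.116) and DGAT2, which makes storage fat (2.22 ± 0.43, adjusted p = 0.216), lay the same way, as did PFKFB1 (2.57 ± 0.46, adjusted p = 0.162) and GCOM1 (2.47 ± 0.47, adjusted p = 0.204). Lower in stroma were the chromatin genes SMARCE1 (-1.43 ± 0.30, adjusted p = 0.284) and HMGA1 (-1.93 ± 0.48, adjusted p = 0.340), the cell cycle phosphatase CDKN3 (-2.57 ± 0.61, adjusted p = 0.340), the zinc transporter SLC39A3 (-2.06 ± 0.47, adjusted p = 0.320) and the protease inhibitor CST1 (-2.94 ± 0.69, adjusted p = 0.335). Of 17473 genes, 10 passed, 1 higher and 9 lower, and 1595 had an unadjusted p under 0.05 where chance gives 874. The 9 lower were copies of SNORD116, described with the epithelial stages, and the 1 higher was ENSG00000257767, with 21.7 to 51.2 TPM in stroma and 0 to 7.73 in epithelium (3.65 ± 0.53, adjusted p = 0.0346). That call was lost under each of the 3 scalings (adjusted p = 0.0607 to 0.0963) and whenever a library other than IDC epithelium 4 or DCIS stroma 2 was left out (0.0569 to 0.312). It was also lost without an expression filter, with paired libraries only, with protein-coding genes alone and among genes of at least 200 nt (0.132 to 0.309). Taking stromal and epithelial labels that share a number as one block made the count 16, and limma called 0 genes among those of at least 200 nt. Without DCIS stroma 2 the count was 54 and without IDC stroma 2 it was 22.

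In epithelium, the question the series title raises is what differs between in situ and invasive carcinoma, with the immune system in view. B cell genes were lower in IDC: MS4A1, the surface antigen CD20, had 124 ± 122 TPM in DCIS (SD, n = 2) and 12.8 ± 9.53 in IDC (n = 4), and the B cell receptor partner CD22 had 31.0 ± 22.4 and 5.53 ± 0.983. Their log2 differences, IDC minus DCIS, were -2.82 ± 0.71 (SE) and -2.08 ± 0.52, and neither passed over all genes (adjusted p = 0.379). All 14 measured B cell markers were lower, with a median of -1.45 (camera adjusted p = 1.1e-06, and adjusted p = 0.932 with an estimated correlation). Adjusted over the list alone, 6 passed, namely BLK, MS4A1, CD22, TNFRSF13C, FCRL1 and BANK1. The median was -2.42 in 1 pair and -0.18 in the other, and without DCIS epithelium 1 it was -0.18 (adjusted p = 0.439). Mean log2(TPM + 1) over the list was 4.37 in DCIS epithelium 1 and 0.84 to 1.77 in the 9 other libraries.

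Other lists were higher in IDC than in DCIS in the epithelial fraction. That fraction held genes of other cell types as well. COL1A1, of the fibroblast list, had 1214 ± 1242 TPM in DCIS epithelium (SD, n = 2) and 1489 ± 648 in IDC epithelium (n = 4). In DCIS stroma it had 1103 ± 1022 and in IDC stroma 1675 ± 1609 (n = 2 each). Whether the share of such cells or the cells themselves differed between the stages was not tested. Macrophage markers were higher in 16 of 21 (median 0.56, adjusted p = 0.0205), with the lysosomal marker CD68 at 0.47 ± 0.45. Fibroblast matrix genes were higher in 18 of 20 (0.50, adjusted p = 0.0155), with collagen COL1A2 at 0.91 ± 0.69, and invasion-associated matrix genes in 16 of 19 (0.31, adjusted p = 0.0459), with the gelatinase MMP2 at 1.44 ± 0.59. Adipocyte markers were higher in 13 of 16 (0.38, adjusted p = 0.0155), with FABP4 at 1.64 ± 0.65, replication-dependent histone genes in 11 of 12 (0.70, adjusted p = 0.0155) and immediate early genes in 17 of 20 (0.49, adjusted p = 0.0208). Each of these had an adjusted p of 0.932 with an estimated correlation, and 0 members passed adjusted over the list alone. Luminal markers (0.30, 12 of 15, adjusted p = 0.153), proliferation (-0.06, 13 of 28 higher, adjusted p = 0.926) and T cell markers (-0.50, 12 of 14 lower, adjusted p = 0.134) did not pass, nor did the 20 other lists. The median of all genes was -0.12 here and 0.0381 with median-of-ratios scaling, and no called list turned its direction under the 3 scalings. Median-of-ratios and upper-quartile scaling ended the invasion call (adjusted p = 0.0684 and 0.0619), as did a pseudocount of 0.1, no block, a block by shared number and protein-coding genes alone (0.0670 to 0.128). The immediate early call was lost with a fixed block or paired libraries only (0.106, adjusted p = 0.487 and 0.443). The 2 pair medians had opposite signs for the immediate early (-0.14 and 0.10), histone (-0.15 and 1.22), fibroblast (-0.20 and 1.51) and adipocyte lists (1.08 and -0.22). Both were above 0 for the macrophage (0.58 and 0.59) and invasion lists (0.29 and 1.58). Without an expression filter all 6 of these calls were lost (0.118 to 0.363). Without DCIS epithelium 2 the fibroblast, invasion, macrophage and histone calls were lost (adjusted p = 0.318 to 0.857), with medians of -0.328, -0.674, 0.133 and -0.0263. Without DCIS epithelium 1 the adipocyte and immediate early medians were -0.357 and -0.0458 (adjusted p = 0.520 and 0.912). IDC epithelium 1 decided the same 4 calls as DCIS epithelium 2 (0.0950 to 0.108), IDC epithelium 2 the adipocyte and immediate early calls (0.0840 and 0.157), and IDC epithelium 3 the invasion and macrophage calls (0.592 and 0.321). The invasion call was also lost without IDC epithelium 4 (0.0640), DCIS stroma 1 (0.0518) or DCIS stroma 2 (0.0517).

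Single genes past the threshold in epithelium were few: 13 of 17473, 2 higher and 11 lower in IDC, with 1505 at an unadjusted p under 0.05 and 874 expected by chance. Of the 11 lower, 9 were copies of SNORD116, a box C/D snoRNA of about 95 nt made from an imprinted cluster. They had 589 to 28551 TPM in the 2 epithelial DCIS libraries, summing to 61950 and 103800 TPM (6.2% and 10.4% of the library's TPM), and were listed at 0 in the other 8. SNORD116-8 had the smallest adjusted p of 4.82e-09. The copies are near-identical, and SNORD116-3 and SNORD116-9 had the same values (13741 and 16648 TPM). SNORD116-5 and SNORD116-7 also shared theirs (1019.8 and 5550.4 TPM). In the counts of this and the other contrasts, the 9 copies are therefore not 9 independent calls. The 15 copies annotated as 83 to 92 nt were listed at 0 in every library, as was the 1 of 102 nt, and in the 8 libraries without SNORD116 no snoRNA of 96 nt or shorter was above 0. Without SNORD116 the shortest snoRNA above 0 in both epithelial DCIS libraries had 99 nt. The other 2 lower were SPRR1A, a precursor of the cornified envelope, with 9.82 and 17.1 TPM in DCIS and 0 in each IDC library (adjusted p = 0.0215), and ENSG00000260170 with 19.6 and 20.6 TPM in DCIS and 0 to 0.34 in IDC (adjusted p = 0.00388). The 2 higher were pseudogenes. SNRPGP10, a processed copy of the spliceosome gene SNRPG, was listed at 0 in both DCIS libraries and had 8.71 to 31.3 TPM in IDC (adjusted p = 0.0296). PMS2P5, a copy of the mismatch repair gene PMS2, had 0 and 2.35 TPM in DCIS and 14.6 to 24.0 in IDC (3.46 ± 0.50, adjusted p = 0.0296). Reads of such copies can be shared with their parents, SNRPG at 52.5 TPM in DCIS and 69.7 ± 20 in IDC and PMS2 at 26 and 19.7 ± 6.88, so both values are uncertain. The SNRPGP10 call was lost without either DCIS library or IDC epithelium 1, 2 or 3 (adjusted p = 0.140 to 0.183), and the PMS2P5 call without any IDC epithelium library or DCIS epithelium 1 (0.103 to 0.184) and narrowly without DCIS stroma 1, DCIS stroma 2 or IDC stroma 2 (0.0503 to 0.0517). Fewer genes were above 0 in DCIS epithelium (18359 and 20457) than in IDC epithelium (22318 to 25438), so a gene listed at 0 in DCIS alone is uncertain as well. Genes of at least 1 TPM overlapped (15282 and 16647 against 15035 to 16510). Small nuclear RNAs held 0.0357% and 0.0554% of the TPM in DCIS epithelium and 0.0898% to 0.239% in IDC epithelium. Next by p, and not passing, were the spliceosomal RNA RNU5B-1 (listed at 0 in DCIS and 15.6 to 142 TPM in IDC, adjusted p = 0.0681), CKS1BP1 (listed at 0 in DCIS and 7.18 to 9.42 TPM in IDC, adjusted p = 0.147) and OLR1, a receptor for oxidised lipoprotein (3.16 ± 0.60, adjusted p = 0.205). Among genes of at least 200 nt, 1 gene passed, and the count was 32 without DCIS epithelium 1 and 39 without DCIS epithelium 2. With the patient as a fixed block in epithelial libraries alone, 5 genes passed, all of them lower. SPRR1A, ENSG00000260170, SNRPGP10 and PMS2P5 were not among them (adjusted p = 0.910), nor did they pass with paired libraries only (0.140 to 0.826). That fixed block also ended the calls of SNORD116-1 (0.133) and of SNORD116-5, SNORD116-7 and SNORD116-26 (0.192 each). The SPRR1A call was also lost without any single IDC epithelium library or DCIS epithelium 2 (0.0757 to 0.141) and with protein-coding genes alone (0.0789). A pseudocount of 0.1 ended the calls of SPRR1A, ENSG00000260170 and PMS2P5 (0.248, 0.0674 and 0.130). A pseudocount of 5 ended those of SNRPGP10 and PMS2P5 (0.222 and 0.0982), as did no expression filter (0.136 and 0.111), and no block that of PMS2P5 (0.0656).

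**Figure D2:**
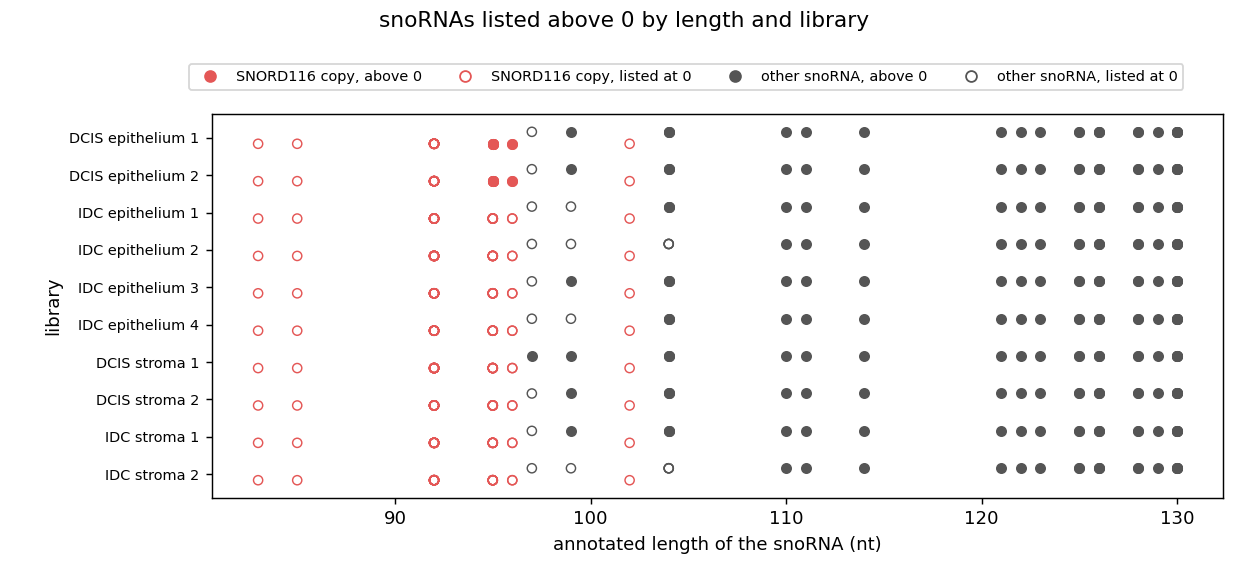
Annotated length (x axis, nt) of the SNORD116 copies (red) and of other snoRNAs with a mean of at least 100 TPM and at most 130 nt (grey) in each library (y axis). Filled points are above 0 and open points are listed at 0; the copies of 95 and 96 nt are filled only in the 2 epithelial DCIS libraries.

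In stroma, luminal, hormone receptor and invasion-associated matrix lists were higher in IDC than in DCIS. MUC1 had 34.9 ± 32.3 TPM in DCIS stroma and 152 ± 90.2 in IDC stroma (SD, n = 2 each), a log2 difference of 2.33 ± 0.72 (SE, adjusted p = 0.477). POSTN had 60.9 ± 4.33 and 404 ± 377 TPM (2.30 ± 0.91, adjusted p = 0.504). The invasion-associated matrix list was higher in 18 of 19 members (median 1.22, adjusted p = 8.8e-06), with MMP11 (3.85 ± 0.85) the 1 that passed adjusted over the list alone. The hormone receptor program was higher in 15 of 16 (1.75, adjusted p = 5.8e-05), and 2 passed adjusted over the list alone: AGR2, a secretory pathway protein (4.14 ± 1.05), and FOXA1, a pioneer factor of the oestrogen receptor (1.75 ± 0.50). Luminal markers were higher in 13 of 15 (1.02, adjusted p = 0.00458). For these 3 lists the adjusted p was 0.950 with an estimated correlation.

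MHC class II genes were higher in 12 of 12 (0.85, adjusted p = 0.00545), with HLA-DRA at 1.41 ± 0.72, and histone genes in 10 of 12 (0.78, adjusted p = 0.0385). Adipocyte markers were lower in IDC stroma in all 16 (-0.97, adjusted p = 0.00123), with FABP4 at -0.94 ± 0.72, as were all 10 Schwann cell markers (-0.74, adjusted p = 0.0194) and 13 of 15 endothelium markers (-0.48, adjusted p = 0.0385). Each of these lists also had an adjusted p of 0.950 with an estimated correlation, and 0 members passed adjusted over the list alone. Basal (1.34, 11 of 15, adjusted p = 0.0653), plasma cell (1.06, 11 of 15, adjusted p = 0.0527) and proliferation lists (0.50, 18 of 28, adjusted p = 0.0688) did not pass, nor did fibroblast matrix (0.26, 12 of 20, adjusted p = 0.781), basement membrane (-0.36, 4 of 17 higher, adjusted p = 0.190) and 17 others. The endothelium call was lost with quantile normalization (adjusted p = 0.0535), the histone call without an expression filter (0.0625) and the Schwann cell call with a mean of at least 5 TPM (0.214). The luminal score over the list was 3.10 in DCIS stroma 1, 4.93 in DCIS stroma 2, and 4.65 and 5.25 in IDC stroma, against 5.14 to 6.22 in epithelium. Without DCIS stroma 1, 6 of the 8 calls were lost (adjusted p = 0.158 to 0.930) and the endothelium median was 0.0806. Without IDC stroma 1 the adipocyte, invasion, MHC class II and Schwann calls were lost (0.138 to 0.335), and without IDC stroma 2 the endothelium, hormone receptor, luminal and histone calls (0.0806 to 0.390).

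**Figure D3:**
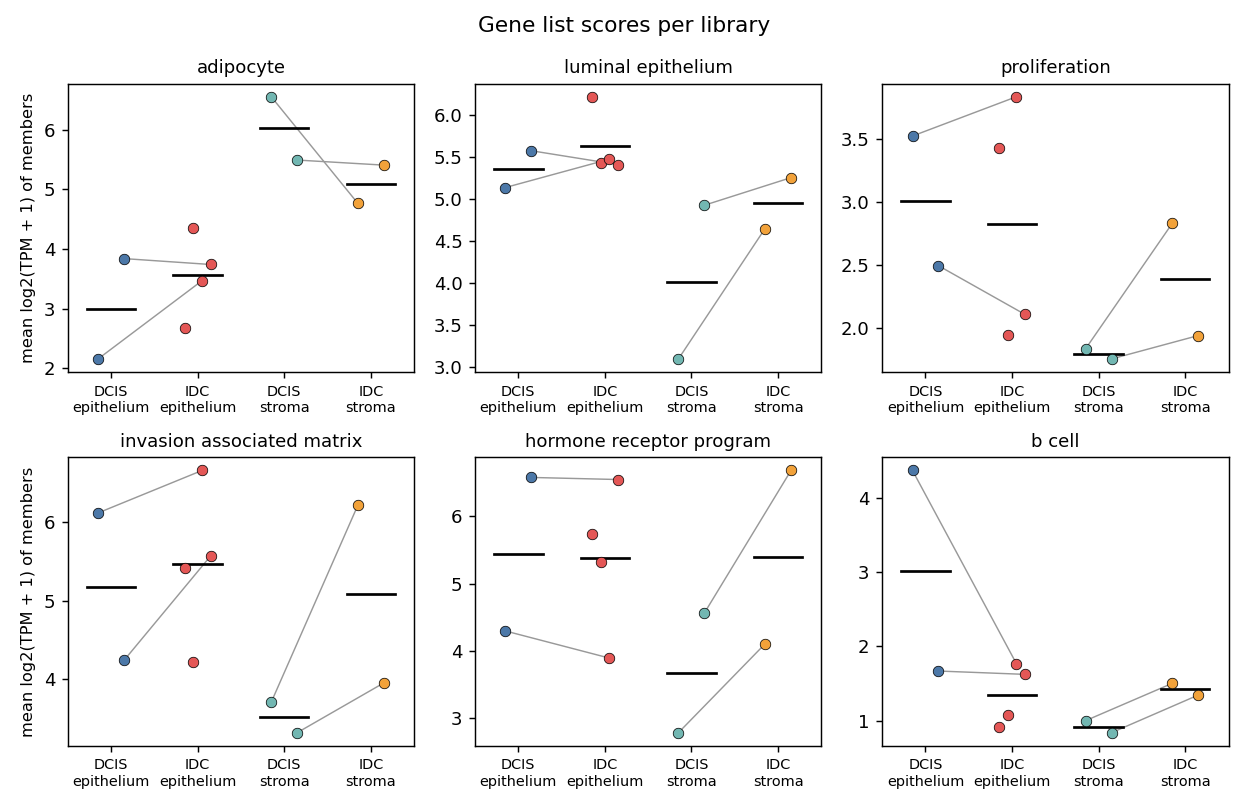
Mean log2(TPM + 1) over the members of 6 gene lists (y axis) in each library, by group (x axis); black lines are group means and grey lines join libraries under one patient label. The B cell score of 4.37 in DCIS epithelium 1 and the adipocyte score of 6.55 in DCIS stroma 1 lie highest in their panels.

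One gene of 17473 passed between the stromal stages, with 1639 at an unadjusted p under 0.05 and 874 expected by chance. It was ENSG00000268465, at 31.71 and 33.96 TPM in the DCIS libraries and listed at 0 in the other 8 (adjusted p = 0.0119). None of the genes that followed passed. Higher in IDC stroma were FBP1, an enzyme of gluconeogenesis (2.05 and 20.4 TPM on average, 2.83 ± 0.50), the adaptor subunit AP2S1 (2.42 ± 0.45), the lipid kinase PIP4K2C (3.09 ± 0.59), PKIB (listed at 0 in both DCIS libraries, 7.91 and 14.4 TPM in IDC), and SNRPGP10 (4.04 ± 0.69), each with an adjusted p of 0.299. Lower were the calcium sensor NCALD (36.1 and 4.11 TPM, -2.85 ± 0.53, adjusted p = 0.299) and, each with an adjusted p of 0.377, the fucosyltransferase FUT10 (57.0 and 9.28 TPM, -2.44 ± 0.51), TESC (-2.66 ± 0.57) and the pseudogenes RRN3P3 (-3.60 ± 0.74) and DNAJC19P9 (131 and 19.8 TPM in DCIS, 0 and 1.67 in IDC). With limma, the count was 0 with a fixed patient block, with paired libraries only and with a mean of at least 5 TPM. It was 441 without DCIS stroma 2, 99 without IDC stroma 2, 12 without DCIS stroma 1, 2 without IDC stroma 1 or either epithelial DCIS library, and 0 without IDC epithelium 1 or 2 (adjusted p of ENSG00000268465 = 0.0573 and 0.0513). A pseudocount of 0.1 also ended that call (0.166).

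The stage difference itself was compared between fractions. B cell markers had a stage difference that was higher in stroma than in epithelium by a median log2 of 1.87 (13 of 14 members, adjusted p = 1.08e-05), with MS4A1 at 4.76 ± 1.06, and 5 members passed adjusted over the list alone (MS4A1, BLK, CD79A, FCRL1 and TNFRSF13C). Adipocyte markers went the other way in all 16 members (-1.43, adjusted p = 8.34e-06), with FABP4 at -2.57 ± 0.97. The hormone receptor program (1.34, 15 of 16, adjusted p = 0.00473), basal markers (1.75, 13 of 15, adjusted p = 0.043), T cell markers (1.22, 12 of 14, adjusted p = 0.043), invasion-associated matrix (0.57, 17 of 19, adjusted p = 0.0449) and ribosomal proteins (0.50, 30 of 33, adjusted p = 0.0449) had a higher stage difference in stroma. Immediate early genes (-0.76, 19 of 20 lower, adjusted p = 0.00181), endothelium (-0.84, 13 of 15, adjusted p = 0.00473) and Schwann cell markers (-0.96, 9 of 10, adjusted p = 0.00652) had a lower one. All 10 lists had an adjusted p of 0.965 with an estimated correlation. In the invasion list, SULF1, which trims heparan sulphate, was the 1 that passed adjusted over the list alone (4.33 ± 1.09). The median of all genes was 0.15 here and -0.0131 with upper-quartile scaling. The ribosomal call was lost with median-of-ratios or upper-quartile scaling and with protein-coding genes alone (adjusted p = 0.105 to 0.125), and also with no block, a block by shared number, a pseudocount of 5 or a mean of at least 5 TPM (0.0605 to 0.145). The invasion and T cell calls were lost with a fixed block (0.0752 and 0.0577) and with paired libraries only (0.164 and 0.0644), and the Schwann cell call with a fixed block (0.0526). A mean of at least 5 TPM ended the basal, invasion, T cell and Schwann cell calls (0.0618 to 0.0864). A pseudocount of 5 ended the basal and invasion calls (0.0904 and 0.114), and no expression filter the basal one (0.0960). Without DCIS epithelium 1, 7 of the 10 calls were lost, the B cell one among them (0.688, adjusted p = 0.127), and the invasion median was -0.141. Without DCIS stroma 1, 6 were lost (adjusted p = 0.112 to 0.976), and the ribosomal median was -0.0237. Without IDC stroma 1, 3 were lost, with an invasion median of -0.563 (adjusted p = 0.625). The other libraries ended 4 calls (DCIS epithelium 2, up to 0.624), 4 (IDC stroma 2, up to 0.773), 3 (DCIS stroma 2, up to 0.290), 3 (IDC epithelium 3, up to 0.563), 2 (IDC epithelium 1, up to 0.128), 2 (IDC epithelium 2, up to 0.163) and 1 (IDC epithelium 4, 0.128). Single genes past the threshold numbered 10, the 9 SNORD116 copies and ENSG00000268465 (adjusted p = 0.0223), with 1236 at an unadjusted p under 0.05. ENSG00000268465 lost its call without any single IDC epithelium library (0.0633 to 0.104), with no block (0.0524), a pseudocount of 0.1 (0.618), a mean of at least 5 TPM (0.664), paired libraries only (0.361), protein-coding genes alone (0.113) and among genes of at least 200 nt (0.188). The fixed patient block gave 6 genes, ENSG00000268465 not among them (adjusted p = 0.974); leaving out one library gave 17 (DCIS epithelium 1), 21 (DCIS epithelium 2), 22 (DCIS stroma 1), 48 (IDC stroma 2) and 188 (DCIS stroma 2).

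Averaged over both fractions, invasion-associated matrix genes were higher in IDC in all 19 members, with a median log2 difference of 0.98 (adjusted p = 7.05e-06, and adjusted p = 0.890 with an estimated correlation). MMP11 (2.29 ± 0.57) was the 1 that passed adjusted over the list alone, and MMP2 had 1.23 ± 0.44 and POSTN 1.33 ± 0.61 (adjusted p = 0.412 and 0.468 over all genes). This call held whichever library was left out. The hormone receptor program (0.96, 15 of 16, adjusted p = 0.00219), luminal markers (0.69, 13 of 15, adjusted p = 0.00219), histones (0.64, 11 of 12, adjusted p = 0.00219) and MHC class II genes (0.60, 11 of 12, adjusted p = 0.00996) were higher, and B cell markers lower (-0.54, 12 of 14, adjusted p = 0.0372). With an estimated correlation each had an adjusted p of 0.890. The B cell call was lost with a fixed block (-0.348, adjusted p = 0.0839), paired libraries only (0.0800), a pseudocount of 0.1 (0.334) and a mean of at least 5 TPM (0.331), and the MHC class II call without an expression filter (0.0533). Without DCIS epithelium 1 the B cell median was 0.155 (adjusted p = 0.876) and the hormone receptor and luminal calls were lost (adjusted p = 0.447 and 0.118). Without DCIS epithelium 2 the MHC class II median was -0.032 (adjusted p = 0.438) and the histone call was lost (0.0997), and without DCIS stroma 1 the luminal, MHC class II and B cell calls were lost (0.0704 to 0.196). The MHC class II call was lost without IDC stroma 1 (0.315), the hormone receptor call without IDC stroma 2 (0.370), and the B cell call without IDC stroma 2, DCIS stroma 2 or IDC epithelium 3 (0.0598 to 0.0697).

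The mean stage contrast had 14 genes past the threshold, 2 higher and 12 lower, with 1862 at an unadjusted p under 0.05. SNRPGP10 (0 to 1.48 TPM in DCIS, adjusted p = 0.00293) and CKS1BP1 (0 to 2.54 TPM in DCIS and 6.51 to 9.81 in IDC, adjusted p = 0.0480), a copy of the cell cycle gene CKS1B, were higher, and the parent CKS1B had 44.2 TPM in DCIS epithelium and 31.5 ± 2.85 in IDC epithelium. Lower were the 9 SNORD116 copies, ENSG00000260170 (adjusted p = 0.00293), ENSG00000268465 (adjusted p = 0.0186) and the pseudogene BMS1P22 (4.58 to 16.1 TPM in DCIS and 0 to 0.6 in IDC, adjusted p = 0.0463). The CKS1BP1 call was lost with a pseudocount of 0.1 or 5 (adjusted p = 0.0832 and 0.0925), no block (0.0934), a block by shared number (0.0682), no expression filter (0.184), a mean of at least 5 TPM (0.153), and whenever a library other than DCIS stroma 2 or IDC stroma 2 was left out (0.0616 to 0.216). The BMS1P22 call was lost with a pseudocount of 0.1 or 5 (0.124 and 0.0970), no block (0.0863), a block by shared number (0.0667), no expression filter (0.104), and median-of-ratios or upper-quartile scaling (0.0536 and 0.0560). Among genes of at least 200 nt CKS1BP1 and BMS1P22 (0.120 each) and ENSG00000268465 (0.0627) did not pass. The ENSG00000268465 call was also lost with a pseudocount of 0.1 (0.256), a mean of at least 5 TPM (0.354) and protein-coding genes alone (0.0565), and the SNRPGP10 call without an expression filter (0.0562). With a fixed block or paired libraries only the calls of SNRPGP10, CKS1BP1, ENSG00000260170, ENSG00000268465 and BMS1P22 were lost (adjusted p = 0.339 to 0.785 and 0.0854 to 0.507). Without any single IDC epithelium library ENSG00000268465 (0.0527 to 0.0869) and BMS1P22 (0.131 to 0.166) did not pass, and BMS1P22 also not without either DCIS epithelium library (0.110 and 0.0881) or IDC stroma 1 (0.200). The count was 6 with a fixed patient block and 9 with the paired libraries only. Among genes of at least 200 nt, 2 genes passed, and without 1 library the count reached 22 (DCIS epithelium 1), 24 (DCIS stroma 1), 80 (IDC stroma 2) and 265 (DCIS stroma 2).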

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

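The tests of SNORD116, of the B cell list and of the stromal stage lists were chosen only after those results were seen. The regroupings of the samples were planned.

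SNORD116 copies held 6.2% and 10.4% of the TPM in the 2 epithelial DCIS libraries and were listed at 0 in the other 8. Reads moved between near-identical copies would leave the sum above 0 elsewhere, and the highest sum in the other 8 libraries was 0 TPM. More transcription of the host locus could not be decided. SNRPN, SNURF and SNHG14 summed were not higher in epithelial DCIS (log2 difference -0.821 ± 0.631, upper 95% bound 0.722). That sum rests on SNRPN and SNURF, because SNHG14 had only 0.12 to 3.06 TPM over the libraries, so it says little about SNHG14. A length below which a library lists no snoRNA cannot be told apart from a difference in this snoRNA: 0 shorter copies were above 0 in the epithelial DCIS libraries and 0 snoRNAs of that length or shorter in the other 8, but of 12 other snoRNAs of 95 to 98 nt 0 were above 0 in the epithelial DCIS libraries. One of the 12, SNORD7 of 97 nt, had 1454 TPM in DCIS stroma 1 and was listed at 0 elsewhere. Without SNORD116 the shortest in the epithelial DCIS libraries had 99 nt, as in IDC epithelium 3, IDC stroma 1 and DCIS stroma 2, so a lower limit in them is shown by SNORD116 alone.

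The lower B cell list in epithelial IDC rested on DCIS epithelium 1, without which the median was -0.183 (adjusted p = 0.439). It did not pass with an estimated correlation (adjusted p = 0.932). A larger epithelial share in the IDC libraries would lower all immune lists alike, and macrophage markers moved apart from B cell markers by 2.10 ± 0.611 (lower 95% bound 0.607). This gap draws on the same library, with a B cell score of 4.37 in DCIS epithelium 1 and 1.67 in DCIS epithelium 2, so it cannot decide. T cell markers lay lower in IDC as well (median -0.50, 12 of 14, camera adjusted p = 0.134). A region rich in B cells in DCIS epithelium 1 may explain the difference as well as the stage would.

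Stromal IDC had higher luminal, hormone receptor and invasion-associated matrix lists than stromal DCIS, and a lower adipocyte list. None of these passed with an estimated correlation (adjusted p = 0.950 each). More epithelium in the stromal IDC regions cannot be told apart from a change in the stromal cells: the luminal median was above 0 in both pairs (the lower 0.353), but this restates the difference. One library could also account for most calls: 2 of the 8 were kept without DCIS stroma 1. A lower share of every stromal cell type alike cannot be told apart from a change of single types, because the interval of fibroblast matrix minus adipocyte change (1.15 ± 1.21, lower 95% bound -1.82) covers 0 widely. A difference between the stages in the stroma itself stays open and untested.

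Regrouping the 10 libraries says nothing about chance for the fraction, because the real split gave 0 genes in the additive limma model used there (1595 had an unadjusted p under 0.05 in the fraction contrast), so all 100 of 100 splits gave as many, the real one included. One split, of DCIS epithelium 1 and 2, DCIS stroma 2 and IDC stroma 1 against the other 6, gave 537 genes. In it DCIS stroma 1 was the only DCIS library on its side, and IDC stroma 1 the only IDC library on the other. DCIS stroma 1 lay at 164 on the first principal component, where the others lay between -33.8 and 10.3. Single libraries may thus lie behind this count, which was not tested. Between stages the real split gave 1 gene, 15 of 100 splits gave as many, the real one among the 15, and the highest other gave 5, so chance could not be excluded. The additive model has no term for a stage difference confined to a single fraction, which goes into its residual spread. These splits therefore do not test the 13 genes called in epithelium or the 14 in the mean contrast. Every split that parts as many label pairs as the real one was fitted besides the 100 drawn. For stage these were 16, of which 3, the real one among them, gave as many, and the highest other gave 1. For fraction they were 10, the highest other gave 17, and with 0 in the real split this says nothing about chance either.

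Of 72 measures tested in the 4 IDC epithelium libraries, 6 had a library far from the other 3, where chance gives about 1 in 20. The luminal score was 6.22 in IDC epithelium 1 against 5.41 to 5.47, and that library had 15040 genes of at least 1 TPM against 16350 to 16510. The checkpoint score was 2.79 in IDC epithelium 3 against 1.38 to 1.54, and the Schwann cell score was 2.76 in IDC epithelium 2 against 1.69 to 1.77. PKIB had 17.4 TPM in IDC epithelium 3 against 6.2 to 8.05, and FUT10 had 13.6 TPM in IDC epithelium 4 against 6.02 to 7.19.

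The stage difference itself differed between fractions, by the interaction term, for 10 genes and 10 lists. The list medians were 1.87 for B cell, 1.75 for basal, 1.34 for hormone receptor, 1.22 for T cell, 0.57 for invasion-associated matrix and 0.50 for ribosomal protein genes. They were -1.43 for adipocyte, -0.96 for Schwann cell, -0.84 for endothelium and -0.76 for immediate early genes. With an estimated correlation 0 of these lists passed (lowest adjusted p = 0.965).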

How the results depend on the processing

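Protein-coding genes alone and genes of at least 200 nt were tests chosen only after the results were seen; the other alternatives were planned. A fixed block cannot give the fraction contrast a value, since as coded no patient label holds both fractions.

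With an estimated correlation, with fry for a shared direction and with fry for either direction, 0 lists passed in each of the 5 contrasts (lowest adjusted p = 0.668, 0.179 and 0.133). Without an expression filter the epithelial stage contrast had 24 genes and 1 list. With a mean of at least 5 TPM the stromal stage contrast had 0 genes and the interaction 5 lists, and a pseudocount of 0.1 gave 3 genes between the stromal stages, 0 of them shared with the 1 above. A fixed block gave 0 genes between the stromal stages, 6 in the interaction, and 6 genes and 10 lists for the mean stage contrast. Within a fraction, a fixed block gave 5 genes in epithelium and 0 genes and 14 lists in stroma. Paired libraries alone gave 0 genes between the stromal stages and 9 for the mean, and a block by shared number gave 16 genes between fractions. No block gave 12, 1, 12, 9 and 12 genes in the epithelial, stromal, fraction, interaction and mean contrasts.

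Protein-coding genes alone gave 1 gene in epithelium, 0 between fractions, 0 in the interaction and 1 for the mean. Genes of at least 200 nt gave 1, 0, 0 and 2. SNORD116 is left out by construction in both. A Benjamini-Hochberg adjusted p can rise when other small p-values are removed, so calls made beside the copies may rest in part on them. Among genes of at least 200 nt, SPRR1A in epithelium went from an adjusted p of 0.0215 to 0.0836. ENSG00000268465 went from 0.0223 to 0.188 in the interaction, where the copies had passed. Between the stromal stages, where no copy had passed, it kept its call (0.0119 and 0.00931). How much of the other changes this explains was not tested.

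Leaving out one library gave 10 to 39 genes and 3 to 11 lists in epithelium, 0 to 441 genes and 6 to 12 lists in stroma, 9 to 54 genes and 10 to 17 lists between fractions, 9 to 188 genes and 4 to 10 lists in the interaction, and 11 to 265 genes and 4 to 11 lists for the mean. In 12 cases a called list's median changed sign. The far end of its range, over the left-out libraries and the other settings together, is given second. Without DCIS epithelium 1 these were adipocyte (-0.357 to 1.26) and immediate early (-0.0458 to 0.796) in epithelium, invasion in the interaction (-0.141) and B cell in the mean (0.155 to -1.15). Without DCIS epithelium 2 they were fibroblast (-0.328 to 1.41), invasion (-0.674 to 1.26) and histone (-0.0263 to 1.22) in epithelium and MHC class II in the mean (-0.032 to 1.25). Without DCIS stroma 1 they were endothelium in stroma (0.0806 to -0.997), plasma cell between fractions (0.0275 to -1.2) and ribosomal in the interaction (-0.0237 to 0.936), and without IDC stroma 1 invasion in the interaction (-0.563 to 1.98).

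Under the other settings, with the same list test, 2171 list values kept their side of the threshold, 51 fell short, 53 newly passed and 0 reversed. For named genes these counts were 557, 30, 4 and 0. Depth is unknown, so no limit from it can be given.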

Other observations

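The counts of snoRNAs by length were chosen only after the SNORD116 result was seen; the list tests were planned.

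Several programs the lists cover did not differ by camera between the stages or the fractions. The median log2 differences for epithelial stage, stromal stage and fraction were 0.12, -0.06 and 0.00 for the EMT program (adjusted p = 0.694, 0.992 and 0.796) and 0.21, 0.19 and 0.06 for oxidative phosphorylation (0.284, 0.849 and 0.796). They were 0.30, 0.06 and 0.10 for hypoxia (0.181, 0.771 and 0.383) and 0.25, 0.53 and -0.44 for the interferon response (0.134, 0.172 and 0.0624). Cytotoxic effectors had 0.36, 0.39 and -0.07 (0.134, 0.703 and 0.388), and checkpoint genes had 0.16, 0.21 and -0.22 (0.675, 0.344 and 0.341). A p that misses the threshold does not show that these were equal.

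Lists that share genes gave these medians in the same order. Basal markers had -0.56, 1.34 and -0.14 (adjusted p = 0.389, 0.0653 and 0.511), and smooth muscle markers -0.41, -0.13 and 0.54 (0.694, 0.771 and 0.0913). The hormone receptor list had 0.02 in epithelium (0.668), and the apocrine list 0.18 in epithelium (0.205) and 0.44 in stroma (0.263). The mast cell list had -0.32, 0.00 and -0.21 (0.893, 0.935 and 0.922), and the lobule list 0.13, -0.64 and 0.16 (0.534, 0.579 and 0.511). Median, mean and camera's direction differed in sign for lists that did not pass (adjusted p = 0.284 to 0.992). In epithelium these were hormone receptor, proliferation, mast cell, EMT and Schwann cell, and in stroma smooth muscle, macrophage, mast cell and EMT. In the interaction they were mast cell, EMT, hypoxia and histone, and in the mean smooth muscle, EMT and lobule. The farthest apart were the median of -0.13 and the mean of 0.42 of the smooth muscle list in stroma.

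The features with the highest TPM were snoRNAs and noncoding RNAs. SNORD3A had a mean of 52160 TPM ± 23800 (SD over the 10 libraries), SNORA73B 29010 ± 9510, SNHG3 17880 ± 6040 and MALAT1 14710 ± 5900. The 50 highest features held 34.4% to 53.2% of a library's TPM. Of 76 other snoRNAs of at most 150 nt with a mean of at least 100 TPM, the 5 shortest were all listed at 0 in at least 1 library, and of the 71 longer ones 1 was.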
